A study of Homo sapiens with 2 samples.

How the data were processed

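RNA was extracted with Trizol from KYSE30 cells grown in RPMI1640 medium, and libraries were made from total RNA with an mRNA library kit, per the labels' protocols. The labels give 1 library of cells with a scrambled hairpin (control) and 1 library of cells with a hairpin against KAT8 (knockdown), and they describe both as infected with virus. The submitters' processing notes name Bowtie2 and HISAT2, without versions or roles. The genome build, the gene annotation and the counting program are not given in the sources used here.

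The authors deposited 1 table of 20332 Ensembl gene identifiers with both libraries side by side. Per the file headers it holds a count and a TPM value for each gene and library. The deposited counts are estimated counts: 14.8% of the control's values above 0 and 14.7% of the knockdown's carry decimals (at most 2), which shows that reads were shared among genes. The authors' TPM columns (abundance corrected for transcript length) each sum to 1000000. The file holds no comparison columns of the authors, so the planned description of such columns does not apply. Symbols were taken from the file. Of the identifiers, 20113 were found in GENCODE release 29 and 20304 in a table of gene names, 617 had no symbol, and gene type, coordinates (GRCh38), transcript length and GC content come from GENCODE release 29, which may not be the annotation the authors used.

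The groups, the size rule, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Estimated counts were rounded to whole numbers, and TMM factors (1.04 for the control and 0.959 for the knockdown library) were computed with edgeR 4.0.16 in R 4.3.3. Counts were divided by the scaled totals to give CPM. The log2 ratio of knockdown over control was taken with a pseudocount of 0.5 CPM added to both values, among genes with a mean of at least 5 CPM over the 2 libraries. The pseudocount makes log2 ratios of low genes smaller than their plain fold, and folds in the text are plain ratios of CPM. Genes at least 2-fold higher or lower were counted by size alone. Each fold has an exact (Clopper-Pearson) 95% interval from the conditional binomial distribution of the counts, which covers counting error only. No test across libraries is possible with 1 library per group, and no p-value was computed.

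The named genes are KAT8 and MYC, then the 15 highest and the 15 lowest log2 ratios among protein-coding genes with a symbol that pass the filter, then up to 4 members of each described list with the largest absolute log2 ratio. A few genes that this rule names are not reported here. Gene lists (38 lists with 1004 different genes) covered MYC and KAT8 biology, the cell cycle, squamous identity, immune and stress responses, metabolism, and markers of other cell types. Some genes stand in more than 1 list. For each list the median log2 ratio over its measured members was set against 10000 random lists matched in 20 bins of mean expression, and members at least 1.5-fold higher or lower were counted. Lists with fewer than 5 measured members have no percentile.

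The control library held 16389063 estimated counts and the knockdown library 14446325. Of these, 5.53% and 5.62% fell on ribosomal protein genes, and the 10 most abundant genes took 11.9% and 11.4%. A gene at the filter of 5 CPM has about 85.5 counts in the control and 69.3 counts in the knockdown library. A count of 0 allows up to 3 counts, which is 0.176 CPM in the control and 0.217 CPM in the knockdown library.

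The steps were tested on simulated data drawn from the control and knockdown levels, with 50 genes changed at each of several fold sizes among 9550 genes. For this comparison the 2-fold rule called 0 of 50 genes changed 1.5-fold, 50 of 50 changed 2.5-fold, 50 of 50 changed 3-fold and 49 of 50 changed 4-fold, and 0 of 9352 unchanged genes. Both simulated libraries were drawn around the mean of the 2 real levels with counting error only. Differences between cultures, infections or library preparations were not simulated, nor was a GC trend. The calls therefore do not measure errors from these sources. Of 200 random lists of 24 genes with no shift, 7.5% fell outside the central 95% of random lists, and with a shift of 0.5 (log2) planted, 96.5% lay in the highest 2.5% of random lists.

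Alternatives set beforehand were total counts without TMM, DESeq2 1.42.0 size factors, pseudocounts of 0.1 and 2 CPM, filters at 1 and 20 CPM or none, a 1.5-fold size, a counting interval that excludes a ratio of 1, and 10 bins for the random lists. Alternatives chosen after seeing the data were the authors' TPM (pseudocount 0.1, mean of at least 1 TPM) and removal of a lowess trend (fraction 0.3) of the log2 ratio on GC content or on transcript length, for 9475 genes with a transcript (99.3% of those filtered). Pathway groups in the closing part come from the KEGG column of the file and were also chosen after seeing the data. Further computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.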

Results

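Gene expression was measured by RNA sequencing in KYSE30, an established human esophageal squamous carcinoma cell line, after infection with virus. The 2 libraries came from cells with a scrambled control hairpin and cells with a hairpin against KAT8, 1 library for each. KAT8 (also called MOF) is a lysine acetyltransferase that works in the MSL and NSL chromatin complexes and is best known for acetylating histone H4. The control library held 16389063 estimated counts with 14073 genes above 0, and the knockdown library held 14446325 with 14041 genes above 0. With 1 library per group no difference below has a replicate check and no p-value is given. The intervals cover counting error only. They assume independent reads, and reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for that error.

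The comparison of the KAT8 knockdown library with the control library addresses what the loss of KAT8 does to the transcriptome, and the series' title directs that question to c-Myc. KAT8 itself was 3.17-fold lower in the knockdown library, whereas the MYC transcript was 1.14-fold lower. Genes of squamous basal keratinocytes, interferon-stimulated genes and genes of antigen presentation were higher in the knockdown library, with median log2 ratios of 0.87, 0.93 and 0.74. Genes that respond to MYC and genes of DNA replication were slightly lower as groups, with medians of -0.18 and -0.19 (-0.30 and -0.31 without the TMM factor). Among protein-coding genes with a symbol, PGF had the highest log2 ratio (15.3-fold higher) and ATP6V0E2 the lowest (17.7-fold lower).

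The target was examined first. KAT8 (ENSG00000103510), which GENCODE release 29 places on chromosome 16 from 31115754 to 31131393 on the + strand of GRCh38, had 368 counts in the control library and 94 in the knockdown library. These counts equal 21.5 and 6.79 CPM (counts scaled to a common library size), a 3.17-fold lower level with a 95% counting interval of 2.52 to 4.02. The authors' deposited TPM values for KAT8 were 25.3 and 7.15. MYC (ENSG00000136997), on chromosome 8 from 127735434 to 127741434 on the + strand in the same annotation, stood at 234 CPM in the control and 205 CPM in the knockdown library, a 1.14-fold lower level with an interval of 1.09 to 1.20. The file gives the mRNA of MYC and holds no measurement of its protein or of protein stability.

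Of 9537 genes with a mean of at least 5 CPM, 466 (4.89%) were at least 2-fold higher and 363 (3.81%) at least 2-fold lower in the knockdown library, so that 56.2% of the genes past this size were higher. The split depended on the setting. Total counts without the TMM factor shifted the median of all genes by -0.12 on the log2 scale and gave 347 higher against 526 lower genes (39.7% higher), with the other settings kept. The authors' TPM values gave 611 against 859 (41.6% higher) among 11205 genes, with another filter and pseudocount as well, so that this move cannot be put down to scaling alone. In the main scaling 73.3% of the genes lay within 1.5-fold. Counting error alone, simulated in 100 draws from unchanged levels, placed 0 genes past 2-fold in either direction. The log2 ratio followed the GC content of the transcript. Its Spearman correlation with GC across 9475 genes, which are not independent replicates, was 0.37, and the median log2 ratio went from -0.25 in the 1895 genes with the lowest GC to 0.27 in the 1895 with the highest.

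**Figure D1:**
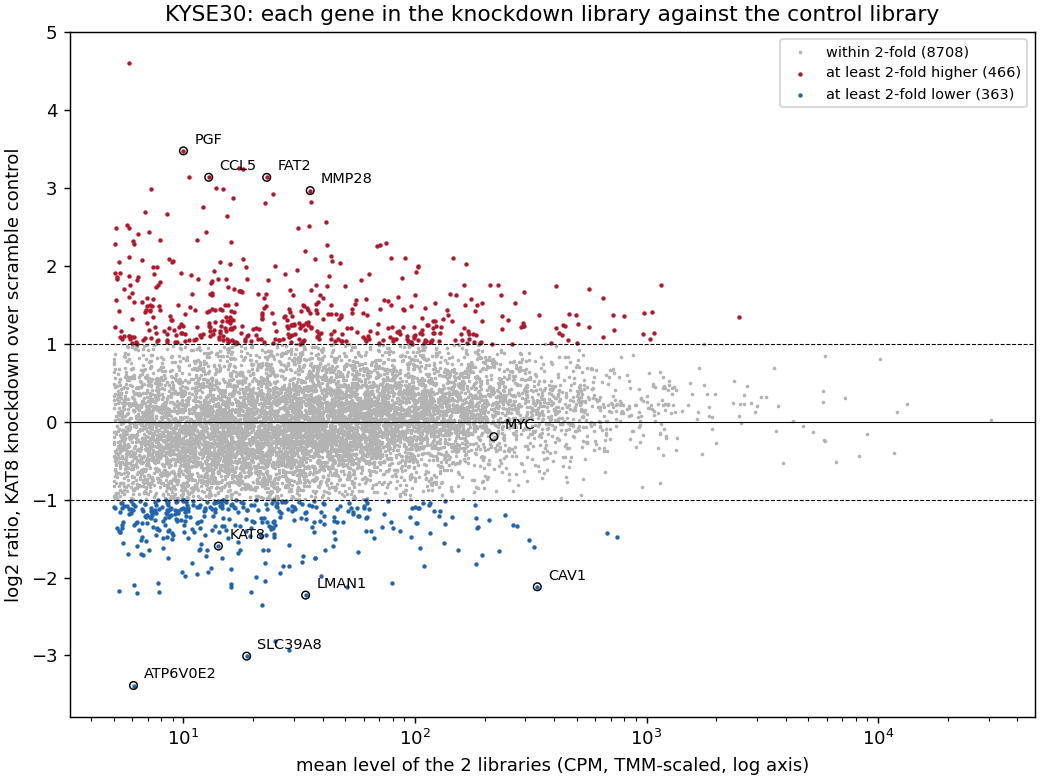
Each point is 1 of 9537 genes, with the mean level of the 2 libraries in TMM-scaled CPM on a log axis and the log2 ratio of knockdown over control on the other axis. Red points (466) are at least 2-fold higher, blue points (363) at least 2-fold lower, dashed lines mark the 2-fold size, circles mark named genes, and the highest point is an identifier without a symbol, which the naming rule left out.

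The 15 protein-coding genes with the highest ratios were 7.46- to 15.3-fold higher, and the lowest lower bound among their counting intervals was 5.72-fold. PGF, a placental growth factor of the VEGF family, went from 1.23 CPM in the control to 18.8 CPM in the knockdown library (15.3-fold, interval 9.79 to 25.1), and IGFBP4, which binds insulin-like growth factors, from 2.87 to 31.8 CPM (11.1-fold, interval 8.26 to 15.2). The complement component C3 was 11.02-fold higher, the chemokine CCL5 10.6-fold, and the lectin LGALS9 9.28-fold. Cell-surface proteins included the large cadherin FAT2 (9.72-fold higher), the VIP receptor VIPR1 (8.19-fold) and the netrin receptor UNC5B (7.58-fold). The remaining genes were CEL, a lipase (10.9-fold), the synaptotagmin SYT8 (10.8-fold), the interferon signalling factor IRF9 (9.11-fold), the metalloproteinase MMP28 (8.28-fold), the aryl hydrocarbon receptor target CYP1A1 (8.21-fold), the keratin KRT17 (7.80-fold) and ASS1 of arginine synthesis (7.46-fold). All 15 were at or below 63.0 CPM in both libraries. Their transcript GC content ran from 52.8% (FAT2) to 67.4% (SYT8), above the middle of 5 equal groups of genes ordered by GC (46.6 to 52.7%). CCL5 and IRF9 carry fractional counts, that is, reads the authors' counting shared with other genes, and their values are less certain. KRT17 has close relatives among the keratins, and CEL has a related pseudogene. For C3 the deposited TPM values of 1.29 and 7.84 stood closer together than the counts did.

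The 15 protein-coding genes with the lowest ratios were 4.36- to 17.7-fold lower in the knockdown library. ATP6V0E2, a subunit of the vacuolar proton pump, had 197 counts in the control and 9 in the knockdown library (17.7-fold lower, interval 9.16 to 39.4). The zinc and metal transporter SLC39A8 was 8.99-fold lower, and TOMM5, a part of the mitochondrial import pore, 7.57-fold lower. CAV1, the main structural protein of caveolae, had by far the highest level of this group and went from 549 to 126 CPM (4.36-fold lower, interval 4.14 to 4.59). Membrane traffic was represented by LMAN1, a cargo receptor between endoplasmic reticulum and Golgi (4.84-fold lower), and SFT2D1 (5.39-fold). The mitochondrial genes AK4, an adenylate kinase, and SLC25A24, a carrier of adenine nucleotides, were 4.46-fold and 4.65-fold lower. The scavenger receptor OLR1 (5.64-fold), EMB (5.49-fold), ZFHX4 (5.23-fold), RDH14 (5.06-fold), IQCG (4.81-fold), LLPH (4.54-fold) and the hair keratin-associated KRTAP2-3 (8.13-fold) completed the group. KRTAP2-3, TOMM5 and AK4 carry fractional counts, and the first of them belongs to a family of near-identical copies. ATP6V0E2 overlaps an antisense gene, ATP6V0E2-AS1, and without stated use of strand their reads cannot be told apart. ZFHX4 had deposited TPM values of 1.78 and 1.45, a much smaller difference than its counts of 226 and 35. The transcript GC content of the 15 genes ran from 37.0% (EMB) to 62.2% (ATP6V0E2). All but ATP6V0E2, KRTAP2-3 and RDH14 lay below the middle of 5 equal groups of genes ordered by GC (46.6 to 52.7%). None of these 15 genes was in a gene list fixed beforehand, against 3 of the 15 highest.

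Gene lists were then compared by their median log2 ratio, set against 10000 random lists of the same size and matched expression. Of 35 lists with enough members, 7 medians lay in the highest 2.5% of random medians and 5 in the lowest 2.5%, where lists of random genes would place 1.75 in all. Genes of a list may be expressed together and some lists share genes, so 1.75 does not measure chance for these lists. With the GC trend removed the numbers were 5 and 2 of 34 lists, since the histone list then had too few members with a GC value, and with TPM they were 7 and 3 of 35. Total counts and TPM shifted the log2 ratios of all genes by a median of -0.12 and -0.09. List medians given below for these 2 settings include that shift, whereas percentiles compare a list with other genes in the same setting. These percentiles describe the 2 libraries and carry no replicate error.

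**Figure D2:**
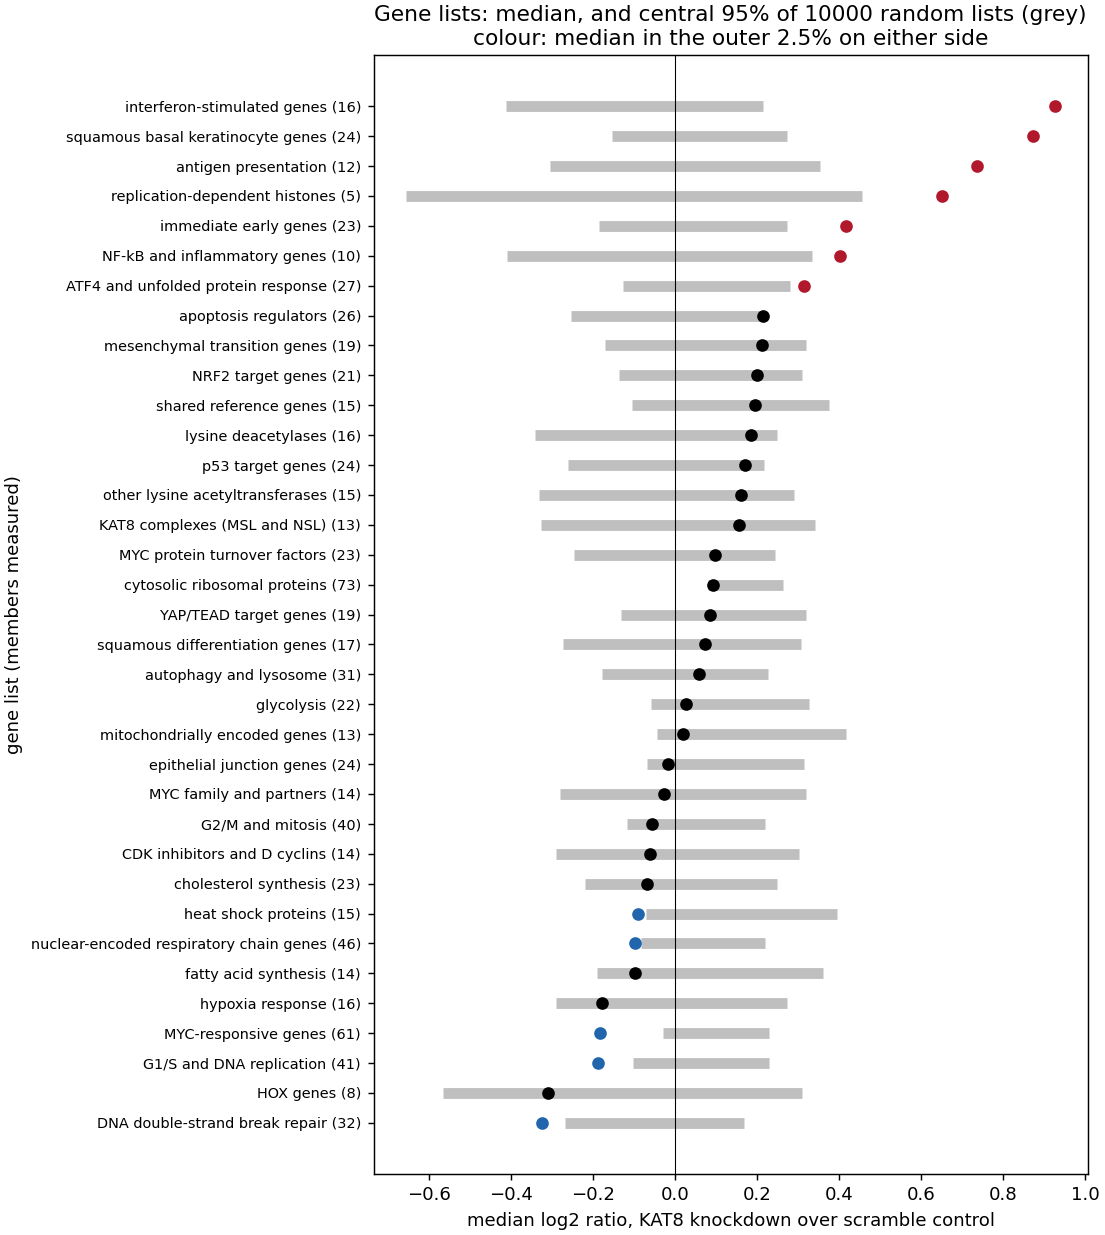
Each row is a gene list with its number of measured members, the dot is its median log2 ratio of knockdown over control, and the grey bar spans the central 95% of 10000 random lists. Coloured dots lie in the outer 2.5% on either side, with interferon-stimulated genes (0.93) and basal keratinocyte genes (0.87) the highest medians and DNA double-strand break repair (-0.32) the lowest.

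Basal keratinocyte genes gave the broadest shift. Of 24 measured members, 16 were at least 1.5-fold higher, 0 were 1.5-fold lower and 8 lay between, and the median of 0.87 lay above all 10000 random lists. The keratin KRT17 was 7.80-fold higher, the neurotrophin receptor NGFR 6.03-fold higher (interval 4.56 to 8.08), TRIM29 3.59-fold and the laminin receptor subunit ITGA3 3.39-fold, the last at 528 CPM in the control and 1792 CPM in the knockdown library. The list's members had a median GC content of 55.8%, above the middle of 5 equal groups of all genes ordered by GC (46.6 to 52.7%). Squamous differentiation genes, which mark the upper layers of the epithelium, had 6 of 17 members at least 1.5-fold higher and 2 lower (median 0.07, percentile 67.8). KRT4 was 2.72-fold higher and NOTCH3 1.96-fold higher, while the cornified envelope gene SPRR1B was 2.14-fold and the protease KLK5 1.91-fold lower. The position of this list depended on the setting. Its median was 0.55 with filters at 1 CPM (19 members, percentile 99.99) and 20 CPM (11 members, percentile 99.63) and with no filter (29 members, percentile 99.99), 0.46 with TPM (percentile 99.97), 0.21 with the GC trend removed (percentile 93.9) and -0.05 with total counts (percentile 68.3). Epithelial junction genes had a median of -0.02 (percentile 7.03) with 5 of 24 higher and 1 lower, among them the claudin CLDN4 at 2.33-fold higher, E-cadherin CDH1 at 1.79-fold higher and KRT7 at 2.35-fold lower. The sign of that median was not stable, at 0.05 with TPM (percentile 70.6), 0.03 with no filter, 0.04 with the length trend removed and -0.12 with the GC trend removed (percentile 2.65). Mesenchymal transition genes had 5 of 19 higher and 2 lower (median 0.21, percentile 86.1), and the median was 0.06 with the GC trend removed (percentile 54.5), 0.10 with total counts and 0.38 with a filter at 20 CPM (percentile 97.2). The matrix genes FN1 and THBS1 were 3.57-fold and 2.78-fold lower, and the membrane protease MMP14 and the cytokine TGFB1 4.02-fold and 2.22-fold higher. YAP/TEAD target genes had 3 of 19 higher and 2 lower (median 0.08, percentile 47.4, or -0.04 with total counts, -0.09 with TPM and -0.03 with the GC trend removed), with AJUBA 2.01-fold higher and CCN1 1.93-fold lower. Of the 8 measured HOX genes, 1 was at least 1.5-fold lower (HOXC10, 3.02-fold) and 0 higher (median -0.31, percentile 22.4).

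Interferon-stimulated genes were the list with the highest median, 0.93, above all 10000 random lists. Of its 39 genes found in the file only 16 passed the filter, and of these 9 were at least 1.5-fold higher and 0 lower. IRF9, the DNA-binding part of the transcription factor activated by type I interferon, was 9.11-fold higher, the mono-ADP-ribosyltransferase PARP14 4.82-fold (interval 3.52 to 6.69), IFI6 4.71-fold and the RNA sensor OAS1 3.67-fold. In the control library IRF9, PARP14 and IFI6 stood at 2.95, 2.98 and 3.16 CPM, so their mean passed the filter only through the knockdown library. Antigen presentation genes had 6 of 12 measured members (19 found) higher and 1 lower (median 0.74, percentile 99.99, or a median of 0.47 with no filter). The class I genes HLA-B and HLA-C were 4.32-fold and 2.71-fold higher, and their reads are shared with related HLA genes. The paired peptide transporter genes went opposite ways, with TAP1 2.32-fold higher and TAP2 2.66-fold lower. In the list of NF-kB and inflammatory genes, 4 of 10 measured members (29 found) were higher and 2 lower (median 0.40, percentile 98.8). CCL5 was 10.6-fold higher, TRAF1 3.88-fold and the NF-kB subunit RELB 2.76-fold, whereas the mitochondrial superoxide dismutase SOD2 was 3.05-fold lower. Median GC content was 51.5% for the interferon list, 57.7% for antigen presentation and 53.3% for the NF-kB list. The NF-kB list moved to percentile 95.005 among the 7 members with a mean of at least 20 CPM.

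**Figure D3:**
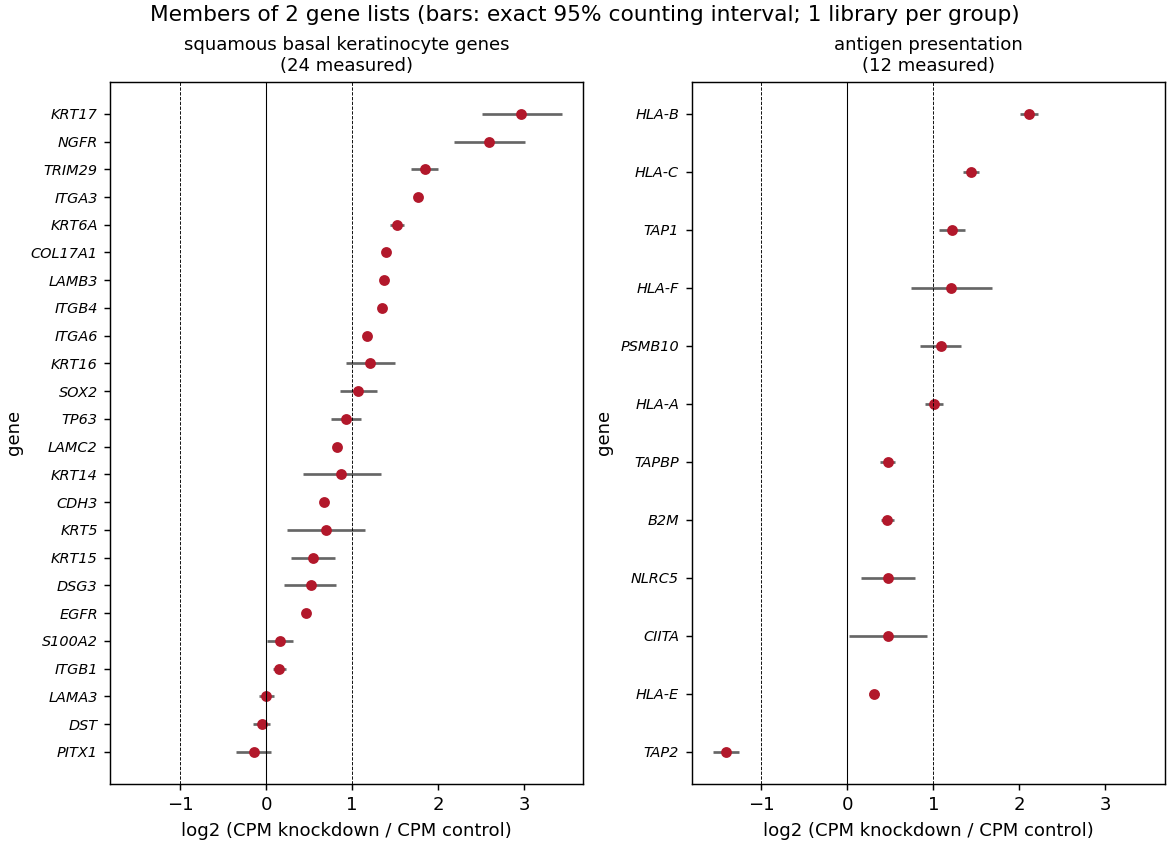
Dots give the log2 ratio of CPM, knockdown over control, for each measured member of 2 lists (24 and 12 genes), and bars give the exact 95% counting interval from 1 library per group. In the basal keratinocyte list 22 of 24 dots lie above 0 and in antigen presentation 11 of 12, where TAP2 is the exception.

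Genes tied to MYC were examined because the title names it. MYC-responsive genes had a median of -0.18, below all 10000 random lists, although most single members differed little. The list's median was -0.30 with total counts and -0.29 with TPM. Of 61 measured, 49 lay within 1.5-fold, 10 were lower and 2 higher. The uracil-DNA glycosylase UNG was 2.66-fold lower and PA2G4, a growth-associated RNA-binding protein, 1.98-fold lower at 567 CPM in the control and 286 CPM in the knockdown library. The higher members were MAP3K6 (2.53-fold) and the nucleoside transporter SLC29A2 (1.88-fold). Within the MYC family and its partners (14 measured, median -0.03, percentile 38.5), the 2 higher members were MXD1 and MXD4, which compete with MYC for MAX, at 3.71-fold (interval 3.05 to 4.54) and 3.09-fold (interval 2.60 to 3.68). MGA was 1.63-fold and the acetyltransferase scaffold TRRAP 1.37-fold lower. Factors of MYC protein turnover had 2 of 23 members higher and 3 lower (median 0.10, percentile 76.6, or -0.02 with total counts and -0.06 with the GC trend removed). AURKA, a kinase known to stabilise MYC proteins, was 2.67-fold lower (interval 2.40 to 2.96) and CIP2A, an inhibitor of the phosphatase PP2A, 1.98-fold lower, while the deubiquitinase USP28 was 2.25-fold higher. All 73 measured ribosomal protein genes lay within 1.5-fold. Their median was 0.09, at percentile 3.58 of random lists. It changed sign to -0.03 with total counts (percentile 4.2) and to -0.0007 with TPM (percentile 10.7), where all genes shifted down.

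Lists of DNA replication and repair had low medians. In the G1/S and DNA replication list, 7 of 41 were at least 1.5-fold lower and 1 higher (median -0.19, percentile 0.17). The median was -0.31 with total counts and -0.30 with TPM. GINS2 of the replicative helicase was 1.84-fold lower, the polymerase subunit POLA1 1.89-fold, the histone chaperone subunit CHAF1B 1.81-fold and ORC6 of the origin recognition complex 1.81-fold. G2/M and mitosis genes had 5 of 40 lower and 0 higher (median -0.06, percentile 10.4). The median was 0.08 with the GC trend removed, -0.18 with total counts and -0.17 with TPM. The mitotic kinesin CENPE was 2.53-fold and the ubiquitin-conjugating enzyme UBE2C 2.17-fold lower. Among the CDK inhibitors and D cyclins 3 of 14 were higher and 1 lower (median -0.06, percentile 33.9). That median turned to 0.39 among the 10 members that passed a filter at 20 CPM (percentile 97.66), to 0.05 with no filter and to 0.02 with the GC trend removed. It went the other way, to -0.17 with a filter at 1 CPM (percentile 14.2) and to -0.18 with total counts. The inhibitor genes CDKN1A, CDKN1B and CDKN2A were 2.09-fold, 2.06-fold and 1.76-fold higher, and the pocket protein gene RBL2 was 1.59-fold lower. DNA double-strand break repair had 10 of 32 members lower and 0 higher (median -0.32, percentile 0.63). RAD50 of the MRN complex was 2.78-fold lower, BRCA1 2.21-fold, RAD51D 1.77-fold and the checkpoint kinase ATR 1.71-fold. The median GC content of the repair list was 42.7%, below that middle group. With the GC trend removed its median was -0.17 and its percentile 7.83, and they were -0.02 and 28.4 among the 13 members with a mean of at least 20 CPM.

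In the ATF4 and unfolded protein response list 11 of 27 members were at least 1.5-fold higher and 0 lower (median 0.32, percentile 98.9). With a filter at 20 CPM its percentile was 97.435, just outside the highest 2.5%, and with total counts its median was 0.19. HERPUD1 of endoplasmic reticulum-associated degradation was 2.58-fold higher, the serine synthesis enzyme PHGDH 2.47-fold, SESN2 2.33-fold and the asparagine synthetase ASNS 2.07-fold. p53 target genes had 6 of 24 higher and 1 lower (median 0.17, percentile 94.3), and apoptosis regulators 5 of 26 higher and 1 lower (median 0.21, percentile 97.2). With total counts these medians were 0.05 and 0.09, and with TPM 0.15 and 0.11. BBC3, the BH3-only protein PUMA and a member of both lists, was 5.61-fold higher (interval 4.21 to 7.56), the antiproliferative BTG2 3.99-fold, the cytokine GDF15 2.60-fold, the death receptor TNFRSF10B 2.33-fold and the BH3-only gene BMF 3.28-fold. The initiator caspase CASP9 was 2.96-fold lower. Immediate early genes had 7 of 23 higher and 3 lower (median 0.42, percentile 99.9), with FOSB 3.47-fold and DUSP6 2.08-fold higher and DUSP4 and SPRED1 2.36-fold and 2.32-fold lower. Their median GC content was 55.4%, and with the GC trend removed the list's median was 0.06 and its percentile 62.7. Heat shock proteins had 0 of 15 higher and 1 lower (median -0.09, percentile 1.99), that 1 being HSP90AA1 at 1.67-fold, and their percentile was 12.5 with the GC trend removed. NRF2 target genes went both ways, with 3 of 21 higher and 4 lower (median 0.20, percentile 84.8). ABCC3 was 3.06-fold and the ferritin heavy chain FTH1 1.99-fold higher, and TXNRD1 and UGDH were 2.49-fold and 2.15-fold lower.

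Nuclear-encoded respiratory chain genes had 4 of 46 lower and 1 higher (median -0.10, percentile 1.68, or 2.53 with the GC trend removed). SDHC of complex II was 3.39-fold lower (interval 2.91 to 3.97), the complex I subunits NDUFB3 and NDUFB5 2.34-fold and 1.91-fold lower, and COX7C 1.83-fold higher. Mitochondrially encoded genes took 10.7% of the counts in the control and 10.4% in the knockdown library. MT-ND6, MT-ND5 and MT-ND1 were 2.18-fold, 1.79-fold and 1.75-fold higher and MT-CO2 1.36-fold lower, around a median of 0.02 (percentile 7.71) that was -0.10 with total counts and -0.07 with TPM. MT-ND6 is encoded on the opposite strand from the other protein-coding genes of the mitochondrial genome, and the counting is not stated to use strand, so reads from the 2 strands cannot be told apart there. Glycolysis genes had 2 of 22 higher and 2 lower (median 0.03, percentile 14.3, or -0.09 with total counts, -0.04 with TPM and -0.07 with the GC trend removed), with the glucose transporter SLC2A3 4.14-fold and PFKFB4 2.85-fold higher. In the hypoxia response list 3 of 16 were higher and 4 lower (median -0.18, percentile 12.2), with VEGFA 2.40-fold higher and HIF1A 2.24-fold lower. Cholesterol synthesis genes had 2 of 23 higher and 1 lower (median -0.07, percentile 24.1), and TM7SF2 was 2.95-fold higher. Fatty acid synthesis genes had 1 of 14 in each direction (median -0.10, percentile 8.87), FADS2 1.54-fold higher and ELOVL6 1.82-fold lower. Autophagy and lysosome genes had 3 of 31 higher and 2 lower (median 0.06, percentile 62.9, or -0.06 with total counts and -0.02 with TPM), with the lysosomal protease CTSD 3.02-fold higher and CTSL 1.96-fold lower.

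Among chromatin genes, the other members of the KAT8 complexes stayed near their control level. Of the 13 measured members KAT8 alone was 1.5-fold lower and 0 were 1.5-fold higher, with MSL1 1.40-fold higher and PHF20L1 1.36-fold lower. The median was 0.16 (percentile 82.4), or 0.03 with total counts and 0.02 with TPM. Other lysine acetyltransferases had 2 of 15 higher and 2 lower (median 0.16, percentile 88.1, or -0.10 with TPM, -0.05 with a filter at 1 CPM and -0.06 with none), namely CREBBP and KAT5 at 1.52-fold and 1.51-fold higher and CLOCK and HAT1 at 1.65-fold and 1.55-fold lower. Lysine deacetylases had 4 of 16 higher and 1 lower (median 0.19, percentile 93.9, or 0.07 with total counts and 0.02 with TPM). Among them HDAC5 was 4.50-fold higher (interval 3.64 to 5.59) and HDAC4 1.83-fold lower. Of the replication-dependent histone genes 5 passed the filter and 3 were higher (median 0.65, percentile 99.3), led by H2AC18 at 2.01-fold. Their median was -0.026 with a filter at 1 CPM, -0.057 without a filter and -0.24 with TPM. Histone genes have near-identical copies and mostly lack poly(A) tails, and the libraries were made with an mRNA kit. Genes commonly used as references had a median of 0.20 (percentile 66.8) with 1 of 15 higher and 1 lower, and POLR2A was 1.55-fold higher. Markers of other cell types were near absent. COL1A1 was the only 1 of 10 fibroblast markers to pass the filter (6.90 CPM in the control and 3.25 CPM in the knockdown library), CD68 the only 1 of 12 leukocyte markers (13.7 and 8.09 CPM), and 0 of 10 endothelial markers passed.

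**Figure D4:**
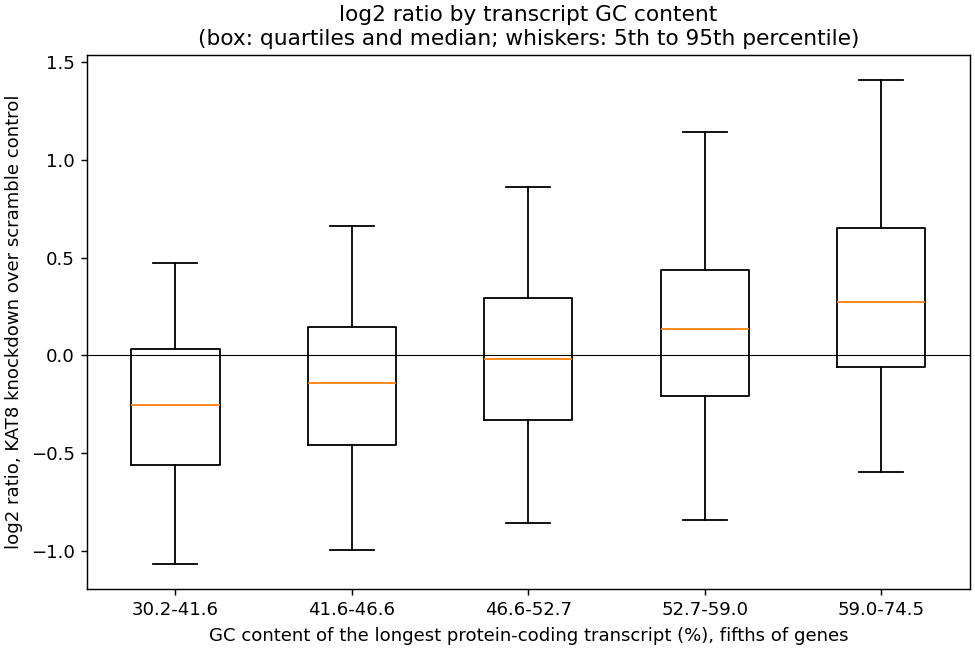
Boxes show the quartiles and median of the log2 ratio of knockdown over control in 5 equal groups of genes ordered by the GC content of their longest protein-coding transcript, and whiskers run from the 5th to the 95th percentile. The medians go from -0.25 in the lowest group to 0.27 in the highest.

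The trend with GC content ran through the genes past 2-fold as well. In the 1895 genes with the lowest GC (30.2 to 41.6%) 16 were at least 2-fold higher and 120 at least 2-fold lower, and in the 1895 with the highest GC (59.0 to 74.5%) 233 were higher and 21 lower. With the trend removed over all genes, 371 genes were at least 2-fold higher and 335 at least 2-fold lower. Transcript length had a Spearman correlation of -0.04 with the log2 ratio across the same genes. Mean CPM had a correlation of 0.20 with it across 9537 genes. The random lists are matched on mean expression, so a list of abundant genes can have a median above 0 and still a low percentile.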

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

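The tests with the authors' TPM and with the GC or length trend removed were chosen after the results were seen. KAT8 stayed lower in the knockdown library, from -1.42 (pseudocount 2 CPM) to -1.81 (TPM) on the log2 scale in 7 alternatives. The counts of genes past 2-fold (466 higher, 363 lower) were 270 and 152 with a filter at 20 CPM, 808 and 675 with none, and 1271 and 1273 at 1.5-fold, and the lower count alone passed 1.5 times its value with a filter at 1 CPM (582) and with TPM (859). Counted over lists and alternatives, 359 percentiles kept their side of the outer 2.5%. The percentiles that moved across it were, at 20 CPM, ribosomal proteins 2.395, CDK inhibitors and D cyclins 97.66 (median from -0.06 to 0.39), double-strand break repair 28.385, squamous differentiation 99.63, NF-kB 95.005 and ATF4 97.435. At 1 CPM they were p53 targets 98.45, squamous differentiation 99.99 and histones 62.045 (median -0.026). With no filter they were p53 targets 98.66, squamous differentiation 99.99 and histones 45.105 (median -0.057). With TPM they were repair 7, squamous differentiation 99.97, heat shock 5.995 and histones 33.9 (median -0.24). With the GC trend removed they were repair 7.83, heat shock 12.475, respiratory chain 2.53 and immediate early genes 62.745. Apoptosis regulators moved to 97.54 at pseudocount 2 CPM and heat shock to 2.7 with 10 bins. A changed filter changes which members are measured, and otherwise the cause was not tested. Counted over named genes and alternatives, 955 log2 ratios stayed within their counting interval and 210 moved beyond it. Of the named genes at least 2-fold higher or lower in the main setting, 0 changed sign in these alternatives. Alternatives that change only the filter were left out of this count. Sign changes of named genes with smaller ratios, and of genes that are not named, were not counted. No paired analysis was possible because each group has 1 library, and no library could be left out for the same reason. Depth limits ratios near the filter, where about 69.3 counts in the knockdown library stand behind a value.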

Other observations

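Tests chosen only after the results were seen were those on KEGG pathways and chromosomes, those with the GC or length trend removed or with TPM, those on shared reads, and that of a library-wide GC bias. The KEGG column of the deposited file gave 297 pathways with 10 to 300 measured genes, many of which share genes, against a background of 4060 annotated genes. In the knockdown library 119 pathways had a median in the highest 2.5% of random lists and 15 in the lowest 2.5%. Lists of random genes would place 7.43 in each tail. Pathway genes may be expressed together and many are shared, so 7.43 does not measure chance for real pathways. With the GC trend removed the numbers of high and low pathways were 103 and 15, of which 93 and 11 were the same pathways. The examples below were picked after their values were seen. The 15 low pathways were aminoacyl-tRNA biosynthesis, ribosome biogenesis, ribosome, nucleocytoplasmic transport, protein export, base excision repair, homologous recombination, cell cycle, oxidative phosphorylation, the citrate cycle, and carbon, purine, porphyrin, glyoxylate and 2-oxocarboxylic acid metabolism. With the GC trend removed, 4 of these left the lowest 2.5%, namely cell cycle (percentile 20.5, median from -0.11 to -0.03), glyoxylate metabolism (6.07), nucleocytoplasmic transport (3.9, median from -0.20 to -0.06) and the citrate cycle (2.76). A low place is relative to random lists of matched expression. The ribosome pathway had a median of -0.02, with 61 of 127 genes above 0, against a random median of 0.12. Oxidative phosphorylation had a median of -0.06 against 0.04. Aminoacyl-tRNA biosynthesis (41 genes, median -0.35) had 9 genes at least 1.5-fold lower and 0 higher, with the arginyl-tRNA synthetase RARS1 2.33-fold lower and the mitochondrial synthetases FARS2 and PARS2 2.39-fold and 2.09-fold lower. Ribosome biogenesis (69 genes, median -0.37) had 14 lower and 1 higher. AFG2A, the RNase P and MRP subunit POP5 and UTP15 of the small-subunit processome were 2.28-fold, 2.04-fold and 1.98-fold lower, and RPP25 was 1.95-fold higher. Base excision repair (31 genes, median -0.38) had 10 lower and 0 higher, among them HMGB1 at 2.40-fold lower and the glycosylase OGG1 at 2.44-fold lower.

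The 119 high pathways were of many kinds, among them signalling and infection sets such as MAPK signaling (177 genes, median 0.23), Ras signaling (122 genes, median 0.25), cytokine-cytokine receptor interaction (53 genes, median 0.39) and human papillomavirus infection (215 genes, median 0.23). No kind was tested against the others, and those described here are examples. ECM-receptor interaction (35 genes, median 0.51) had 16 genes at least 1.5-fold higher and 4 lower. Its integrin ITGA3 and collagen COL6A1 were 3.39-fold and 2.90-fold higher and its secreted matrix proteins FN1 and THBS1 3.57-fold and 2.78-fold lower. Cell adhesion molecules (45 genes, median 0.47) had 20 higher and 3 lower, counting HLA-B and HLA-C of the antigen presentation list, with CNTN1 2.79-fold and the integrin ITGB8 2.65-fold higher. Axon guidance (116 genes, median 0.31) had 38 higher and 8 lower. The receptors UNC5B, PLXNA2 and EPHB6 were 7.58-fold, 4.05-fold and 4.21-fold higher, and the semaphorin SEMA4B was 3.40-fold higher. By chromosome, the median log2 ratio was 0.20 over 640 genes of chromosome 19 and -0.25 over 153 genes of chromosome 13, and 0.01 and -0.06 with the GC trend removed. Not all medians moved toward 0 with that removal. Chromosome 18 (139 genes) went from -0.01 to 0.11 and chromosome X (276 genes) from 0.05 to 0.07.

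Basal keratinocyte genes were higher in the knockdown library (24 genes, median 0.87). Removing the GC trend left a median of 0.868 (95% bootstrap interval over members 0.511 to 1.17), removing the length trend left 0.877 (0.582 to 1.37), and the 18 members that are not keratins had a median of 0.872 (0.33 to 1.35), each above all 10000 random lists. The length trend over all genes was near absent (Spearman -0.04), so its removal could hardly change the median and does not decide on length. The GC trend spanned group medians of -0.25 to 0.27, so its removal could take away only part of 0.87. That size argues against the GC trend over all genes as the whole cause. The members that are not keratins argue against reads shared among keratins as the whole cause. Squamous differentiation genes, with a median of 0.07, also had medians of 0.55 with filters at 1 and 20 CPM or none and 0.46 with TPM, so a shift of basal genes alone was not shown. The KAT8 knockdown was not tested as the cause, and any other difference between the 2 cultures, infections or library preparations stays open, since 1 library per group cannot separate it from the knockdown.

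Interferon-stimulated and antigen presentation genes as 1 set of 28 genes had a median of 0.92. It was 0.781 (0.432 to 1.02) with the GC trend removed, 0.937 (0.481 to 1.17) with the length trend removed, and 0.527 (0.444 to 1.26) over the 18 genes outside the HLA, IFIT and OAS families, at percentile 99.97 of random lists. As for the basal list, the near absent length trend makes the length test unable to decide. The size of the GC trend argues against that trend over all genes as the whole cause. The value outside the 3 families argues against shared reads as the whole cause, although shared families could account for part of the size. Other filters were applied to each list, not to the set. With no filter the medians were 0.90 for interferon-stimulated genes (37 members, percentile 100) and 0.47 for antigen presentation (17 members, percentile 99.76). They were 1.19 and 1.03 with a filter at 1 CPM, and 1.07 and 1.01 at 20 CPM. The unfiltered values argue against the filter as the whole cause for either list. The filter could account for part of the antigen presentation median. The KAT8 knockdown and a response to virus or hairpin that differed between the cultures, both of them infected, stay open and untested.

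The log2 ratio went up with GC content by 0.245 per 10 percentage points over all genes (interval 0.232 to 0.258). Among the 2379 genes with the highest CPM the slope was 0.180 (0.156 to 0.205). This value argues against low counts or the filter as the whole source, but it is smaller than over all genes, so they could account for a part. Within ribosomal protein and respiratory chain genes together (119 genes) it was 0.174 (0.091 to 0.264), and a GC bias that differs between the 2 libraries is thus a candidate explanation. A biological origin stays open, because KAT8-dependent promoters may differ in GC content and promoters were not tested.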
